A study of Mus musculus with 15 samples.

How the data were processed

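The samples are single-end RNA-seq libraries of mouse biliary epithelial cells, prepared with a TruSeq RNA v2 kit per the labels' protocols, which does not mark the strand. The labels name the source as an established line from bile ducts of adult animals. The series title speaks of 3D structures in vitro and its design text of structures in vivo, and the sources used here do not settle which growth form was sampled. Samples were grouped by solvent or 4-OH tamoxifen and by time, from their titles: 3 ethanol and 4 tamoxifen libraries at 12 h, and 4 and 4 at 24 h. An ethanol library numbered 2 at 12 h was not analysed here.

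Reads were aligned and compared with HISAT2, mm10 and DESeq2 per the submitters' processing notes, which give no versions, roles or order. The counting tool, the annotation and the design formula are not given in the sources used here. The values are the authors' comparison of tamoxifen with ethanol, in 1 table per time with 24421 gene symbols each, and the times were normalised separately. Per the file headers, the authors' tables give the mean normalised count of a gene (baseMean), the log2 fold change with its standard error, the Wald score (statistic), the p-value and the adjusted p-value. The deposited score equals the log2 fold divided by its standard error up to a largest deviation of 1.10e-13. The adjusted p-value is blank in the authors' tables for genes of low mean, so 13044 genes have one at 12 h and 11648 at 24 h, of 15704 and 15819 with a p-value. At 12 h 1 gene with a fold, Snai2, has no p-value in the authors' deposited table; it was named after its value was seen.

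The direction of the folds was checked on the values at 12 h. Genes with a single read fall on 7 distinct lowest means at 12 h, of which 3 lie with negative and 4 with positive folds, as the 3 ethanol and 4 tamoxifen libraries require for tamoxifen over ethanol. At 24 h there are 8 such means, 4 on each side, a split that is the same in either direction, so it does not check the direction there. The direction at 24 h was taken to be that at 12 h, and 0 genes were called in opposite directions at the times. The lowest means also give the authors' size factors, 0.955 to 1.05 at 12 h and 0.934 to 1.07 at 24 h, and with them library totals in genes of 13.3 to 14.5 M at 12 h and 11.1 to 12.6 M at 24 h. With these factors, the means of all 2603 genes at 12 h and all 2800 genes at 24 h in the range of up to 12 reads matched exactly 1 set of whole reads per library within a tolerance of 1e-11. A total of 3 reads over all libraries corresponds to a mean of 0.410 to 0.449 at 12 h and 0.352 to 0.401 at 24 h. The recovered reads were not assigned to samples and enter no comparison between groups. Intervals and floors cover what the standard errors or counts hold, and reads without molecular identifiers are not independent molecules.

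The tests written before the data were examined assumed counts per library, with comparison columns alone as the stated fallback, which applied. Genes were called at an adjusted p under 0.05 in the authors' Wald test with Benjamini-Hochberg adjustment. No test at gene level was run here within a time. The difference between times was tested as the difference of log2 folds over the root of the summed squared standard errors, with Benjamini-Hochberg adjustment over genes with a p at both times. Overlap of calls was tested per direction with a one-sided Fisher's exact test. The 24 gene lists were fixed before the data were examined and tested with cameraPR of limma (version 3.58.1, R 4.3.3) on the authors' Wald score with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists; list members under older symbols were matched through RefSeq synonyms. A correlation estimated from residuals needs values per library and was not computed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. The 95% intervals are 1.96 standard errors wide on each side. The standard error of a gene was compared with the running median over 201 genes of similar mean.

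The named genes follow a rule fixed before the data were examined. It takes Klf5; the 10 largest rises and 10 deepest falls per time among called genes with a mean of at least 50 normalised counts; up to 4 called members with the smallest p of each list that passed an adjusted p under 0.05 or held at least 3 called members; and up to 5 genes per direction for the difference between times. Symbols that start with Gm and a number, end in Rik or contain -ps were counted and not named. Not every gene that the rule selects is named in the text. Other named genes are said to have been chosen after their values were seen. Positions come from GENCODE on GRCm38, the assembly that mm10 names, and 90 of the 92 genes that the rule selected were found there under the tables' symbols. Of them, 7 share over 10% of their exon bases with another gene on the opposite strand: Ube2c (22.8%), Gadd45a (19.1%), Ppp1r1b (15.7%), G6pdx (13.6%), Hmgcs1 (12.1%), Adamts9 (12.0%) and Pla2g7 (11.0%). The kit keeps no strand, so reads of these overlaps cannot be assigned to 1 gene.

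The steps were tested on simulated data. For the difference between times, noise was drawn at the tables' standard errors over 14981 genes. Changes were placed only in genes with a mean of at least 50 normalised counts at both times. Of these, 83 of 100 changes of 1 log2 unit and 99 of 100 changes of 2 log2 units were recovered, and 2.67% of the calls were false. In the data this Wald test held 1.64% of genes at an unadjusted p under 0.05, fewer than such noise gives, so the simulated rates need not hold there. The list test, on 15000 simulated genes, called 40 of 40 shifted lists and 0.109% of the unshifted lists. The simulated genes were independent and a single size of shift was used. These rates therefore do not cover lists whose members are correlated beyond the preset value, or smaller shifts. Whole reads were read back from simulated means in 2513 of 2513 genes at 12 h and 2481 of 2481 at 24 h. Alternatives tried were adjustment over all genes with a p, minimum means of 10 and 100, thresholds of 0.01 and 0.1, a minimum absolute log2 fold of 0.5, folds centred on the median, and other settings of the list test.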

Results

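RNA was profiled in an established line of mouse biliary epithelial cells, the cells that line bile ducts. The line carries a tamoxifen-inducible Cre recombinase (CreERT2) and floxed alleles of Klf5, a Krüppel-like zinc finger transcription factor. Addition of 4-OH tamoxifen activates the recombinase, and ethanol is the solvent control. At 12 h there were 3 ethanol and 4 tamoxifen libraries, and at 24 h there were 4 ethanol and 4 tamoxifen libraries, 15 in all. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. All samples share the inducible genotype, so the effects of tamoxifen, of Cre activity and of Klf5 loss are contained in the same contrast. The files hold the authors' comparison of tamoxifen with ethanol at each time and no value per library. The normalised read counts in the authors' deposited tables sum to 13.9 M per library on average at 12 h, over 24421 gene symbols, and to 11.8 M at 24 h. Fold changes are given as log2 of tamoxifen over ethanol with the authors' standard error (SE).

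The targeted gene was examined first. Klf5 lies on chromosome 14 from 99298691 to 99315036 on the forward strand of GRCm38. Klf5 fell in the authors' deposited table by 1.29 on the log2 scale at 12 h (SE 0.23), to 40.9% of the ethanol level, with an adjusted p of 9.75e-06 in the authors' Wald test. At 24 h it fell by 1.72 in the authors' deposited table (SE 0.08), to 30.4% of the ethanol level, with an adjusted p of 9.51e-107 in the same test. The value covers the whole gene and the labels do not state which exons are floxed, so reads from exons outside the deleted part are counted as Klf5. The difference between the times, -0.43 (SE 0.24), did not pass the threshold and had an unadjusted p of 0.0802 in the Wald test of Klf5.

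To find the early response, tamoxifen and ethanol were compared at 12 h. Falls outnumbered rises. At an adjusted p under 0.05 in the authors' deposited table, 95 genes fell and 28 rose, of 13044 with an adjusted p, and 35 of the falls and 7 of the rises were at least 2-fold. At an unadjusted p under 0.05 there were 769 genes in the authors' deposited table, 4.90% of those with a p, no more than the 5% of a test without differences, so the 12 h calls can miss changes. Among called genes with a mean of at least 50 normalised counts, the deepest falls in the authors' deposited table were Dlk2, an EGF-like membrane protein related to Notch ligands, at -2.15 (SE 0.31), and Cobl, an actin nucleator, at -2.01 (SE 0.33). They were followed in the authors' deposited table by the potassium channel gene Kcnu1 at -1.93 (SE 0.19) and the alarmin cytokine Il33 at -1.81 (SE 0.20). Sprr2h, of a small proline-rich protein family, stood at -1.64 (SE 0.19) in the authors' deposited table, the ephrin receptor Epha5 at -1.64 (SE 0.24), and the mannose receptor Mrc1 at -1.62 (SE 0.19). Ppp1r1b at -1.55 (SE 0.35) and the glycosyltransferases Gcnt3 at -1.50 (SE 0.26) and Mgat3 at -1.46 (SE 0.21) completed the 10 deepest falls in the authors' deposited table.

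Among called genes with a mean of at least 50 normalised counts, the largest rises at 12 h were smaller than the deepest falls. Adamts9, a secreted metalloproteinase of the ADAMTS family, rose by 1.28 (SE 0.30) and Smpdl3b rose 2.0-fold (SE of the log2 fold 0.29) in the authors' deposited table. Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose by 0.92 (SE 0.19) and haptoglobin (Hp) by 0.90 (SE 0.26) in the authors' deposited table. The monocyte chemokines Ccl2 and Ccl7 rose by 0.89 (SE 0.12) and 0.71 (SE 0.20) in the authors' deposited table. Papss2, which makes the sulfate donor of sulfotransferases, rose by 0.74 (SE 0.21) in the authors' deposited table. Stra6, a receptor for retinol uptake, rose by 0.71 (SE 0.19) and G6pdx, the rate-limiting enzyme of the pentose phosphate pathway, by 0.71 (SE 0.13) in the authors' deposited table. Smpdl3b, Hp and Papss2 had adjusted p between 0.0545 and 0.0587 when the authors' Wald p were adjusted over all genes with a p.

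Gene lists fixed before the data were examined were then tested at 12 h with cameraPR on the authors' Wald statistic. Of 24 lists, 6 lay above and 2 below the other genes. The list of basement membrane components and integrins was lower (adjusted p = 0.00124): 3 of its 24 measured members fell, none rose and 21 did not pass the threshold, and 3 fell adjusted over the list alone. Among the members that fell in the authors' deposited table were Lamb3, at -0.75 (SE 0.17), and the integrin gene Itgb6, at -0.99 (SE 0.16). The list of NF-kB and inflammation genes was higher (adjusted p = 0.00377), with 2 members up and 1 down of 20 measured in the authors' deposited table, Ccl2 and Ccl7 against Il33; adjusted over the list alone, 4 rose and 1 fell. The interferon list was higher (adjusted p = 0.00272), with 1 member of 20 called, and 2 adjusted over the list alone. That member was the chemokine gene Cxcl10, which rose by 2.08 (SE 0.47) from a low level, a mean of 22.4 normalised counts, in the authors' deposited table. The TGF-beta and mesenchymal list was higher (adjusted p = 0.0157), with 1 called member of 19; adjusted over the list alone, 1 rose and 1 fell.

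A further 4 lists passed the test at 12 h with few or no called members. The hepatocyte marker list (16 measured, adjusted p = 0.0162), the G2 and mitosis list (25 measured, adjusted p = 0.0299) and the cilium list (20 measured, adjusted p = 0.0426) lay higher in cameraPR, each with 0 called members by the authors' Wald test, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. Their median log2 folds were 0.32, 0.08 and 0.10. The list of Krüppel-like factors lay lower (adjusted p = 0.0426) with Klf5 as its 1 called member of 15 and 2 adjusted over the list alone, and without Klf5 its adjusted p was 0.41. In the lists that did not pass, the keratin gene Krt7 of the biliary list (1 down of 21), Ctgf of the YAP target list (1 down of 22) and Sprr1a of the stratified epithelium list (1 down of 14) were the called members, named after their values were seen. Adjusted over the list alone, 2 YAP targets and 1 gene each of the biliary, stratified epithelium, EGFR and hypoxia lists fell, and the cameraPR adjusted p of the lists that did not pass ranged from 0.19 to 0.98. No member was called by the authors' Wald test in the lists of G1/S and DNA replication, p53 targets, estrogen receptor targets, tight junctions and polarity, adherens junctions and desmosomes, Notch, EGFR and MAPK response, cholesterol synthesis, hypoxia and glycolysis, unfolded protein and integrated stress response, fibroblast and stellate, endothelial or immune markers. At an unadjusted p under 0.05 those lists held 0, 2, 1, 1, 0, 4, 3, 0, 1, 1, 0, 0 and 0 members in that order. The fibroblast, endothelial and immune lists had median means of 1.14, 5.89 and 1.56 normalised counts at 12 h. Members under 1.84, the lowest mean with an adjusted p, could not be called. The 0 calls of these lists therefore do not show unchanged genes. With a preset correlation of 0.05 the calls of 2 lists remained, those of the basement membrane and interferon lists (adjusted p = 0.0475 and 0.0475), and with the log2 fold in place of the statistic 0 lists passed. Among genes with a mean of at least 100 normalised counts the TGF-beta, interferon and cilium lists no longer passed (adjusted p = 0.20, 0.21 and 0.26), and in the rank-based test the basement membrane, Krüppel-like factor and TGF-beta lists did not (adjusted p = 0.26, 0.40 and 0.0610).

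The same comparison at 24 h addressed the later response. Of 11648 genes with an adjusted p in the authors' deposited table, 760 fell and 687 rose at an adjusted p under 0.05, and 67 of the falls and 27 of the rises were at least 2-fold. Among called genes with a mean of at least 50 normalised counts Dlk2 again fell most, at -3.49 (SE 0.32) in the authors' deposited table, and its level was 8.93% of ethanol. The annexin gene Anxa8 stood at -1.94 (SE 0.09), Sprr2h at -1.92 (SE 0.11) and Itgb6, the beta chain of an integrin that activates TGF-beta, at -1.89 (SE 0.33) in the authors' deposited table. Tigit, an inhibitory receptor known from lymphocytes, was at -1.73 (SE 0.23) and Msln, the cell-surface glycoprotein mesothelin, at -1.69 (SE 0.06) in the authors' deposited table. Cobl at -1.63 (SE 0.20), Ms4a4b at -1.63 (SE 0.20) and Xkr9 at -1.49 (SE 0.19) completed, with Klf5, the 10 deepest falls in the authors' deposited table. Sprr2h, Ms4a4b and Ly6c1 belong to families of similar genes, and their values are uncertain where reads were shared within the family. Msln had the smallest p of these falls and a high level, a mean of 4662 normalised counts in the authors' deposited table.

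**Figure D1:**
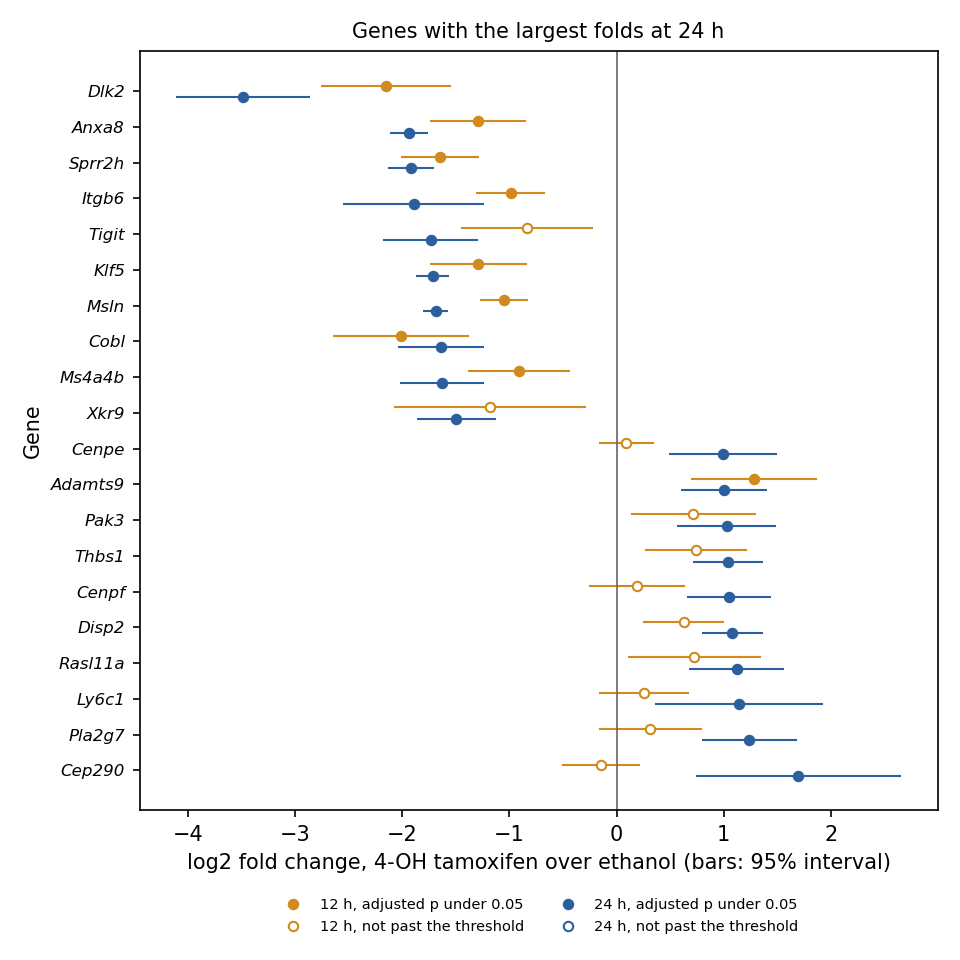
Log2 fold changes, tamoxifen over ethanol, of the 10 deepest falls and 10 largest rises at 24 h, with 95% intervals from the authors' SE in the deposited tables; orange is 12 h, blue is 24 h and filled points passed an adjusted p under 0.05. Dlk2 lies at -3.49 at 24 h, and Cep290 lies at 1.70 with the widest interval among the rises.

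Of the rises at 24 h above the same minimum mean, Cep290, a centrosomal protein of the ciliary transition zone, had the largest at 1.70 in the authors' deposited table, with an SE of 0.49 that is 3.75 times that of genes of similar level. The lipoprotein-associated phospholipase gene Pla2g7 rose by 1.24 (SE 0.23), Ly6c1 by 1.15 (SE 0.40), Rasl11a by 1.12 (SE 0.22) and Disp2 by 1.08 (SE 0.15) in the authors' deposited table. The kinetochore genes Cenpf and Cenpe rose by 1.05 (SE 0.20) and 0.99 (SE 0.26) in the authors' deposited table. The SEs of Cenpe and Ly6c1 were also large, at 3.18 and 2.58 times those of genes of similar level. Thrombospondin (Thbs1) rose by 1.04 (SE 0.16), the kinase gene Pak3 by 1.03 (SE 0.24) and Adamts9 rose 2.0-fold (SE of the log2 fold 0.21) in the authors' deposited table. Ly6c1 had an adjusted p of 0.0503 when the authors' Wald p were adjusted over all genes with a p.

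Genes of G2 and mitosis rose together at 24 h. Of the 25 list members, 15 rose in the authors' deposited table, none fell and 10 did not pass the threshold, and 20 rose adjusted over the list alone; the cameraPR adjusted p was 1.71e-12. The proliferation antigen gene Mki67 rose by 0.61 (SE 0.13), the spindle factor Tpx2 by 0.40 (SE 0.08) and the anaphase ubiquitin enzyme Ube2c by 0.49 (SE 0.12) in the authors' deposited table, beside Cenpf and Cenpe. These folds are larger than the list's median of 0.31. Beside that of Cenpe, the SEs of Cenpf, Mki67 and Ube2c were 1.79, 1.79 and 1.70 times those of genes of similar level, and that of Tpx2 was 1.24 times. The list of G1/S and DNA replication genes held 0 called members of 25 by the authors' Wald test and 2 at an unadjusted p under 0.05, both lower (cameraPR adjusted p = 0.28), and it passed as lower in the rank-based test (adjusted p = 0.0231). With the log2 fold in place of the statistic the mitosis list had an adjusted p of 0.0966.

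**Figure D2:**
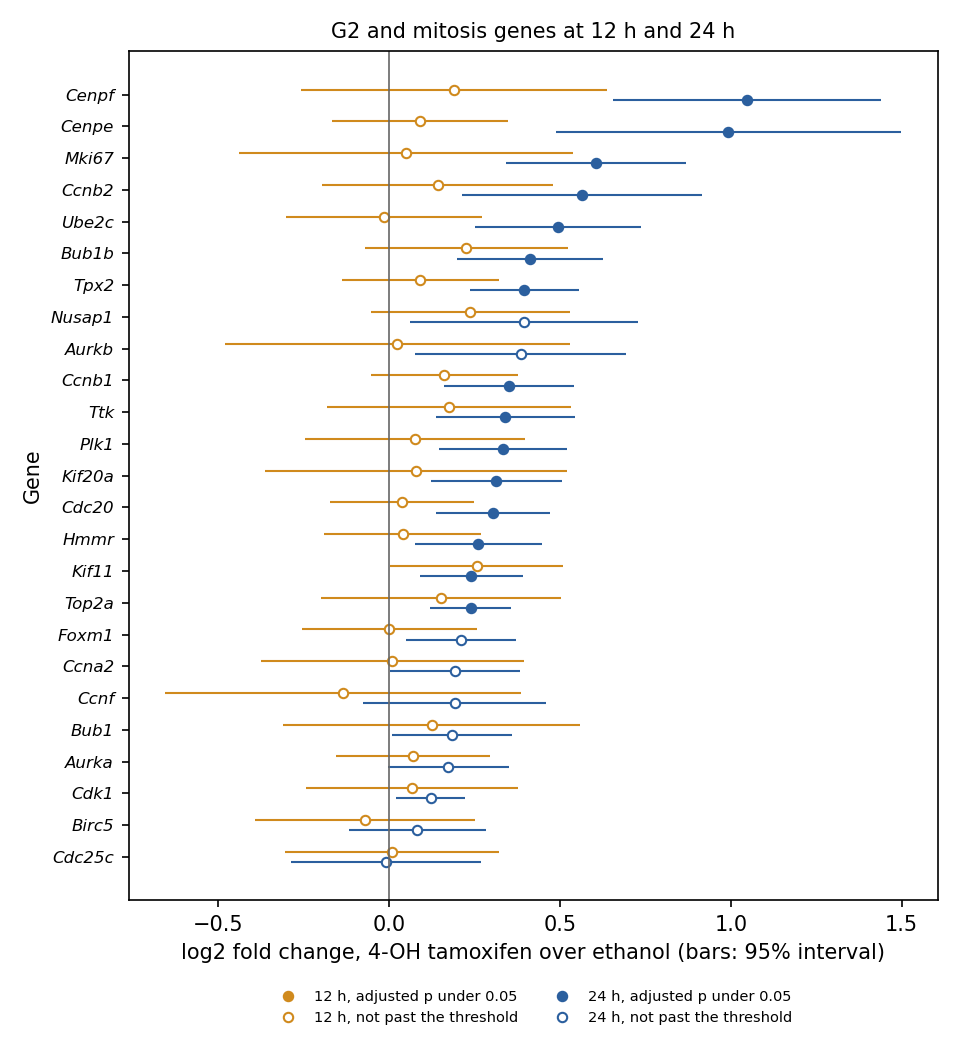
Log2 fold changes, tamoxifen over ethanol, of the 25 members of the G2 and mitosis list with 95% intervals from the authors' SE in the deposited tables; orange is 12 h, blue is 24 h and filled points passed an adjusted p under 0.05. At 24 h 15 members passed, all higher, and at 12 h 0 passed.

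The list of Krüppel-like factors lay lower than other genes at 24 h (cameraPR adjusted p = 3.62e-08), with a median log2 fold of -0.14. Of 15 measured members, 5 fell, none rose and 10 did not pass the threshold in the authors' deposited table, with 5 adjusted over the list alone. Beside Klf5 these were Klf3 at -0.42 (SE 0.05), Klf6 at -0.40 (SE 0.09), Klf13 at -0.17 (SE 0.05) and Klf9, named after its value was seen, at -0.15 in the authors' deposited table. Without Klf5 the adjusted p of the list was 0.0144, and with the log2 fold in place of the statistic it was 0.67.

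Matrix and adhesion genes moved both ways at 24 h. Of 23 measured basement membrane and integrin genes, 6 fell and 3 rose in the authors' deposited table and adjusted over the list alone, and the cameraPR adjusted p was 0.63. Nid1 (nidogen) stood at -0.34 (SE 0.06) and the laminin gene Lamb2 at -0.33 (SE 0.05), against 0.32 (SE 0.05) for the collagen gene Col4a1, in the authors' deposited table. Adherens junction and desmosome genes counted 4 falls and 0 rises among 16 in the authors' deposited table and adjusted over the list alone (cameraPR adjusted p = 0.0741). They were Ctnna1 (alpha-catenin) at -0.15 (SE 0.03), Mllt4 (afadin) at -0.19 (SE 0.04), the desmosomal cadherin Dsg2 at -0.21 (SE 0.07) and Perp at -0.20 (SE 0.06) in the authors' deposited table. Among 25 tight junction and polarity genes, 3 fell and 1 rose in the authors' deposited table and adjusted over the list alone (cameraPR adjusted p = 0.71). The falls were the scaffold gene Tjp1 at -0.28 (SE 0.05), Cldn2 at -0.34 (SE 0.06) and F11r at -0.11 (SE 0.03), and the rise was Cldn4 at 1.24 (SE 0.44) from a mean of 11.6 normalised counts, in the authors' deposited table. Cldn4 had an adjusted p of 0.0542 when the authors' Wald p were adjusted over all genes with a p.

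Biliary identity genes were also split at 24 h. Of 22 measured markers, 3 rose and 2 fell in the authors' deposited table, as they did adjusted over the list alone (cameraPR adjusted p = 0.30). Tspan8 fell by 0.59 (SE 0.08) and the biliary keratin gene Krt19 by 0.46 (SE 0.09), while the biliary transcription factor gene Onecut2 rose by 0.29 (SE 0.06), in the authors' deposited table. Hepatocyte markers counted 2 rises and 0 falls of 16, the same adjusted over the list alone (cameraPR adjusted p = 0.24). Fibroblast and stellate (9 measured), endothelial (8) and immune (7) markers held 0 called members at 24 h by the authors' Wald test and 0 at an unadjusted p under 0.05 (cameraPR adjusted p = 0.88, 0.88 and 0.97). The stratified epithelium list held 0 of 11, with 2 at an unadjusted p under 0.05 (cameraPR adjusted p = 0.79). Median means of the fibroblast, endothelial, immune and stratified epithelium lists were 0.39, 2.43, 0.61 and 2.74 normalised counts. These lie under 7.34, the lowest mean with an adjusted p at 24 h, so many members could not be called. The 0 calls therefore do not show that these genes were unchanged.

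None of the signalling lists passed the list test at 24 h. Of 22 EGFR and MAPK response genes 4 fell and 3 rose in the authors' deposited table, and 6 fell and 5 rose adjusted over the list alone (cameraPR adjusted p = 0.84). Egfr stood at -0.32 (SE 0.06), its ligand gene Ereg at -0.43 (SE 0.10) and the MAPK phosphatase gene Dusp4 at -0.24 (SE 0.06), against 0.52 (SE 0.11) for the ETS factor Etv5, in the authors' deposited table. Of 22 YAP targets 3 fell and 2 rose in the authors' deposited table, and 3 fell and 4 rose adjusted over the list alone (cameraPR adjusted p = 0.52). Ctgf fell by 1.05 (SE 0.10), Ajuba by 0.40 (SE 0.06) and Fjx1 by 0.32 (SE 0.11), while Nuak2 rose by 0.26 (SE 0.07), in the authors' deposited table. Of 17 Notch pathway genes 2 fell and 2 rose in the authors' deposited table, and 3 fell and 2 rose adjusted over the list alone (cameraPR adjusted p = 0.38). The target Hey1 fell by 1.63 (SE 0.40) from a mean of 15.5 normalised counts and the receptor Notch2 by 0.16 (SE 0.04), while Rbpj and Maml3, of the nuclear effector complex, rose by 0.23 (SE 0.07) and 0.33 (SE 0.11), in the authors' deposited table. Of 20 TGF-beta and mesenchymal genes 3 rose and 1 fell in the authors' deposited table, and 3 rose and 2 fell adjusted over the list alone (cameraPR adjusted p = 0.0847). Fibronectin (Fn1) rose by 0.53 (SE 0.05) and Tgfb2 by 0.91 (SE 0.24), and the membrane metalloproteinase Mmp14 fell by 0.14 (SE 0.04), in the authors' deposited table. The NF-kB and inflammation list held 1 rise and 1 fall of 18 (adjusted p = 0.52), the interferon list 1 rise of 21 (adjusted p = 0.24) and the estrogen receptor target list 1 rise and 1 fall of 13 (adjusted p = 0.97) in cameraPR and the authors' deposited table, and the counts were the same adjusted over the list alone. The NF-kB list had a median log2 fold of 0.24 at 12 h and 0.21 at 24 h, and the interferon list 0.31 and 0.32. Neither passed cameraPR on the Wald score of the difference between times, a test chosen after results were seen (adjusted p = 0.26 and 0.51). A loss of either rise by 24 h is therefore not shown. Of 15 NF-kB members with a mean of at least 50, 10 had over 2 times the usual SE at 24 h.

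Among metabolic, stress and organelle lists at 24 h, the hypoxia and glycolysis list was lower (cameraPR adjusted p = 0.0144), with 4 of 21 members down and 1 up in the authors' deposited table, and 6 down and 1 up adjusted over the list alone. The glycolytic genes Pgk1 and Hk2 fell by 0.33 (SE 0.05) and 0.19 (SE 0.05) and Ndrg1 by 0.27 (SE 0.05), while the oxygen sensor Egln3 rose by 0.52 (SE 0.12), in the authors' deposited table. The list's median fold was -0.07 and its mean 0.09, so that median and mean differ in sign, and its adjusted p was 0.11 with a preset correlation of 0.05. With the log2 fold in place of the statistic the list's direction turned upward (adjusted p = 0.77). The cilium list was higher (cameraPR adjusted p = 0.0144), with 3 of 20 members up and none down in the authors' deposited table, and 4 up adjusted over the list alone. They were Cep290, the fibrocystin gene Pkhd1 at 0.43 (SE 0.14) and the intraflagellar transport gene Ift140 at 0.39 (SE 0.12) in the authors' deposited table. Its adjusted p was 0.0647 without members whose SE was over 1.5 times that of genes of similar level, Cep290 among them, and 0.11 with a preset correlation of 0.05. Of 20 unfolded protein and integrated stress response genes 6 fell and 2 rose in the authors' deposited table, and 7 fell and 3 rose adjusted over the list alone (cameraPR adjusted p = 0.0731). The serine synthesis gene Phgdh fell by 0.36 (SE 0.05), Atf3 by 0.33 (SE 0.08), Herpud1 by 0.31 (SE 0.07) and Ddit3 (CHOP) by 0.24 (SE 0.06) in the authors' deposited table. Of 22 cholesterol synthesis genes 2 rose and 1 fell in the authors' deposited table and adjusted over the list alone (cameraPR adjusted p = 0.28). Dhcr7 rose by 0.38 (SE 0.14) and Hmgcs1 by 0.25 (SE 0.07), and Lss fell by 0.27 (SE 0.08), in the authors' deposited table. Dhcr7 had an adjusted p of 0.0524 when the authors' Wald p were adjusted over all genes with a p. Of 25 p53 targets 3 fell and 2 rose in the authors' deposited table and adjusted over the list alone (cameraPR adjusted p = 0.92). Gadd45a fell by 0.33 (SE 0.06), Plk3 by 0.36 (SE 0.11) and Perp by 0.20 (SE 0.06), and the apoptosis regulator Bbc3 rose by 0.27 (SE 0.09), in the authors' deposited table.

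The 2 times were then set side by side. Of the genes with an adjusted p at both times, 78 fell at both and 18 rose at both in the authors' deposited tables. Independent lists of the same lengths would share 6.14 and 1.59 (one-sided Fisher's exact test, p = 1.37e-77 and 1.73e-16), and 0 genes were called in opposite directions. The times share no library. Across 14981 genes with a p at both times, which are not independent replicates, the log2 folds correlated with Pearson's r of 0.18 and Spearman's rho of 0.33. Genes with few reads weigh on this value: with a mean of at least 100 normalised counts at both times r was 0.66. Among genes called at either time r was 0.81, but those were chosen by their folds, which itself can raise r. Genes lower at both times included Dlk2, Cobl, Sprr2h, Anxa8, Msln, Il33, Itgb6 and Ctgf, and genes higher at both times included Adamts9, Pdk4 and Stra6, in the authors' deposited tables.

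**Figure D3:**
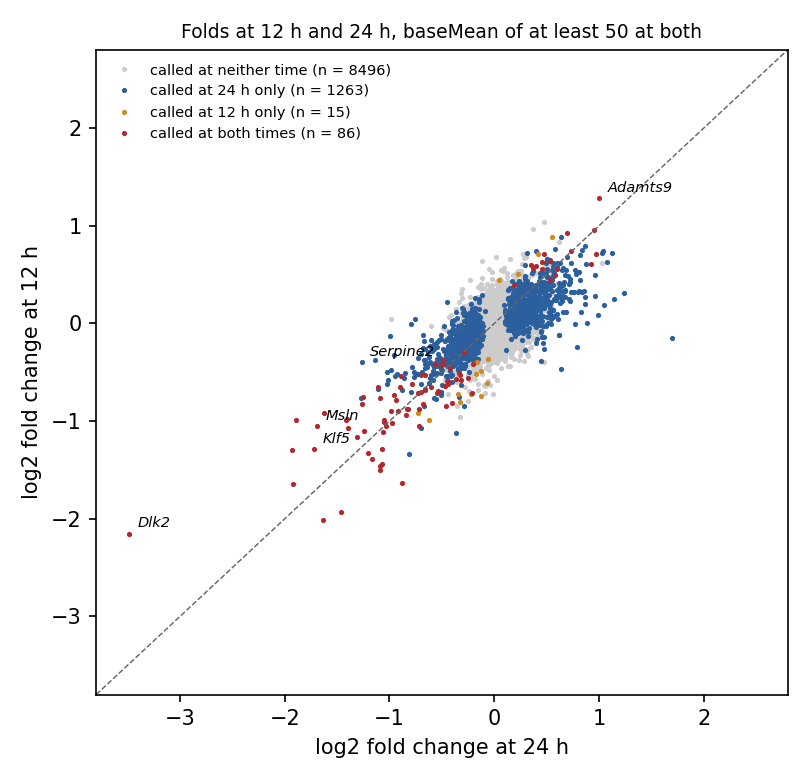
Log2 fold changes, tamoxifen over ethanol, at 12 h (vertical) against 24 h (horizontal) for 9860 genes with a mean of at least 50 normalised counts at both times in the authors' deposited tables; colours show the time at which a gene passed an adjusted p under 0.05 and the dashed line marks equal folds. The 86 genes called at both times lie in the lower left and upper right corners, with Dlk2 at -3.49 and -2.15.

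The difference between the times was tested directly, gene by gene. Of 14981 genes, 2 passed an adjusted p under 0.05 (Wald test with Benjamini-Hochberg adjustment), both more negative at 24 h. Serpine2, an inhibitor of serine proteases on chromosome 1, went from -0.39 (SE 0.14) at 12 h to -1.27 (SE 0.09) at 24 h in the authors' deposited tables, a difference of -0.87 (SE 0.17, adjusted p = 0.00346). Msln, on chromosome 17, went from -1.05 (SE 0.11) to -1.69 (SE 0.06) in the authors' deposited tables, a difference of -0.64 (SE 0.13, adjusted p = 0.00485). At an unadjusted p under 0.05 the test held 245 genes, 1.64% of those tested, fewer than the 5% of a test without differences, so it is conservative and can miss differences. The other genes called at 24 h and not at 12 h are therefore neither shown to differ between the times nor shown to be alike.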

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

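The tests named here were chosen before their results were seen, except those of depth, library number, genes of up to 12 reads, transcript length and GC content for the mitosis genes, and the list test of the difference between times, which were chosen after.

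Serpine2 and Msln drew attention because their folds differed between the times: the difference of log2 folds, 24 h minus 12 h, was -0.87 (SE 0.17) for Serpine2 and -0.64 (SE 0.13) for Msln in the Wald test on the authors' deposited tables. Of the 24 lists, 2 differed between the times in cameraPR on the difference score, which compares folds and not levels. Folds of the G2 and mitosis list were more positive at 24 h than at 12 h (adjusted p = 6.01e-11, and 3.44e-06 with a preset correlation of 0.05). Those of the list of biliary markers were also more positive at 24 h (adjusted p = 0.0154). The biliary call was lost with a preset correlation of 0.05 (adjusted p = 0.15) and among genes with a mean of at least 100 normalised counts (adjusted p = 0.0707).

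The mitosis list had a median log2 fold of 0.31 at 24 h against 0.08 at 12 h. Length and GC content of transcripts do not account for the median at 24 h: against genes of the same length and GC bin the median of the 25 members was 0.32, and all 25 lay above their bin. A few members of unusually large standard error do not account for the median at 24 h either, since the 19 members within 1.5 times the usual standard error had a median of 0.24. Neither check was made at 12 h, so they do not bear on the difference between the times. Tamoxifen itself, Cre activity and the loss of Klf5 remain open, because all are contained in the contrast and none was tested apart from the others; that the rise follows from Klf5 loss is a hypothesis. A batch that lines up with treatment was not told apart either. The rise is relative to ethanol at 24 h. Over both arms together, in values normalised separately, 25 of 25 members had lower levels at 24 h than at 12 h.

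Fewer genes were called at 12 h (123) than at 24 h (1447), and standard errors were larger at 12 h. Lower depth in reads is excluded, because the summed normalised counts at 12 h were 1.17 times those at 24 h. This sum counts reads, which are not independent molecules, so it does not exclude fewer distinct molecules at 12 h. The 1 missing ethanol library would raise standard errors 1.08 times, while the median ratio was 1.94. At 12 h 2 of the 7 libraries had fewer single-read genes, the second lowest library 0.517 times the third lowest. Low counts there are thus clumped, which may account for part of the error of genes of up to 12 reads. Among such genes, reads per detected gene were 1.398 to 1.97 over the 12 h libraries. At 24 h they were 1.32 to 1.37, so clumping at 12 h may reach beyond the 2 libraries. For genes with a mean of at least 1000 the ratio of standard errors was 2.43, which an added counting error that shrinks with level does not account for. These 2 libraries lie on opposite sides, with 50 single-read genes on the side of positive folds and 62 on that of negative folds. Whether they differ in another way that widens the error at every level was not tested, so that stays open. A smaller response at 12 h stays open: the slope of 12 h on 24 h folds was 0.637 (95% bootstrap interval over genes 0.598 to 0.680) among genes called at 24 h, a choice that favours large folds at 24 h, and 1.03 among genes called at 12 h, so the direction depends on which time selects the genes.

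Folds at the times were also correlated among the 8496 genes called at neither time with a mean of at least 50 normalised counts, with Pearson's r of 0.44 across genes, which are not independent replicates. Length and GC content do not account for this, since r was 0.436 for folds against genes of the same bin. A few genes of large fold do not either, since r was 0.414 without genes above an absolute log2 fold of 0.5. The times share no library, so shared controls add nothing; a response below the threshold at both times and a batch that lines up with treatment at both times were not told apart by any test here.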

How the results depend on the processing

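All settings here were written before the data were examined, except the lists without Klf5, the lists without members of large standard error and the difference restricted to genes with an adjusted p at both times. No paired analysis was possible because the tables hold no values per library; for the same reason fits that leave out a library, other splits of the samples, another normalisation, edgeR, limma-voom, other count filters, fry and an estimated correlation were not run, so whether 1 library decides a call is unknown.

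At a threshold of 0.01 the calls were 79 at 12 h and 854 at 24 h, and shared calls were 9 up and 50 down. With a minimum absolute log2 fold of 0.5, 359 genes were called at 24 h. These counts follow from the stricter limit. In all other settings counts of genes lay within 1.5 times the main count, and the 2 genes that differed between times were called in each. Centring changed the 24 h calls to 730 up and 699 down. Pearson's r between the times moved from 0.18 to 0.618 with a minimum mean of 10 and 0.661 with 100. The main value is thus lowered by genes of few reads. Spearman's rho was 0.327. Among genes called at either time r was 0.813, but those were chosen by their folds, so that value does not bear on read number. At 12 h the number of lists past the threshold went from 8 to 2 with a preset correlation of 0.05, 5 in the rank-based test, 5 with a minimum mean of 100 and 0 with the log2 fold; the cause was not tested. At 24 h it went from 4 to 2 and 0 with the first and last of these. The hypoxia list reversed with the log2 fold (adjusted p = 0.769). Over all settings and times, calls of single lists were lost in 27 further instances and gained in 1. Of 97 named calls beside Klf5, 91 remained past the threshold when adjusted over all genes with a p and 97 after centring. Klf5 was called at both times after centring. The medians subtracted were -0.00604 at 12 h and -0.00716 at 24 h. Shifts this small could not undo the calls of Klf5 and could hardly change the other named calls. These outcomes therefore say little about the normalisation. Genes of few reads limit what the tables can show: the lowest mean with an adjusted p was 1.84 at 12 h and 7.34 at 24 h.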

Other observations

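The genes and groups named here were chosen after their values were seen, except the lists, and no explanation is offered for them. Some genes of the S100 and annexin families of calcium-binding proteins fell at 24 h, and neither family was tested as a list. Of 6 measured S100 genes with a mean of at least 50 normalised counts, 5 fell and 0 rose in the authors' deposited table, among them S100a10 at -0.79 (SE 0.06) and S100a6 at -0.73 (SE 0.06). Of 11 annexin genes 4 fell, 2 rose and 6 had negative folds in the authors' deposited table: Anxa2, which binds S100a10, stood at -0.61 (SE 0.04), Anxa3 at -0.57 (SE 0.05) and Anxa11 at -0.31 (SE 0.08), beside Anxa8. Ahnak, a giant scaffold protein that binds the complex of Anxa2 and S100a10, was at -0.93 (SE 0.17) at 12 h and -0.84 (SE 0.05) at 24 h in the authors' deposited tables.

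Single genes of retinoid handling and of pericellular proteolysis were also lower, and neither theme was tested as a list. The retinol dehydrogenase gene Rdh10 stood at -0.99 (SE 0.15) and -1.41 (SE 0.10) and the retinal dehydrogenase gene Aldh1a1 at -1.38 (SE 0.23) and -1.17 (SE 0.14) at 12 h and 24 h in the authors' deposited tables, while the retinol receptor Stra6 was higher. The urokinase receptor gene Plaur was at -1.10 (SE 0.24) and -1.24 (SE 0.08) and the collagenase gene Mmp13 at -1.17 (SE 0.32) and -1.31 (SE 0.12) in the authors' deposited tables. The plasminogen activator gene Plat was at -0.52 (SE 0.10) at 12 h and -0.18 (SE 0.12) at 24 h in the authors' deposited tables, the latter not past the threshold.

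Genes of the integrated stress response had large standard errors at 12 h, and their list did not pass the test there. Of the 20 members of the unfolded protein and integrated stress list with a mean of at least 50 normalised counts, 14 had a standard error over 2 times that of genes of similar mean at 12 h, against 1 at 24 h and 1.73% of all genes above that mean at 12 h. In the authors' deposited table for 12 h Trib3 had a log2 fold of 0.20 with an SE of 1.27, Atf3 -0.75 with 1.28 and Chac1 0.47 with 1.08. At 24 h the same held for the NF-kB and inflammation list, with 10 of its 15 members above that mean over 2 times the usual standard error, against 1.47% of all such genes, and in part for the EGFR and MAPK list, with 8 of 21; Cxcl1 had a log2 fold of 0.01 with an SE of 0.39 in the authors' deposited table for 24 h.

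Levels also differed between the tables, over both arms together. As a share of all normalised counts, the G2 and mitosis list had a median log2 difference of -1.77 at 24 h against 12 h, lower in 25 of 25 members, the G1/S list -1.05 (24 of 25) and the cholesterol list -1.47 (22 of 22), against -0.05 for all genes with a mean of at least 50. The stress list stood at 0.70, with 2 of 20 members lower. Mki67 went from 245 to 44.6 counts per M. The tables were normalised separately and time cannot be told apart from batch here, so these values carry no test.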
